A study of Dictyostelium discoideum with 12 samples.

How the data were processed

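RNA sequencing libraries of Dictyostelium discoideum were analysed, from 5 strains developed together or from mixed RNA of the 5 strains, at 4, 8 and 12 h. Per the labels' protocols, cells grown in axenic medium were starved on filters, polyadenylated RNA was selected, 100 ng was broken to about 200 bases, and barcoded libraries were read at 50 bases on a Genome Analyzer II. Titles of 8 of the 12 samples name a time other than the developmental time label, while the description field matches that label in 12 of 12 samples. Groups and the replicate numbers 3 and 4 were therefore taken from the description, and grouping by titles was run as an alternative. Titles also give the opposite arm for the libraries described as 8 h, and the time label does not name the arm. The direction of every 8 h difference between arms therefore rests on the description field. The series calls the replicates biological but does not say what they share, so p-values hold only as far as replicates are independent.

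For each library the authors deposited raw read counts per gene, per the file headers. They also deposited RPKM values, counts scaled by gene length and library total, per the file headers and the values themselves. A check showed that each RPKM equals the count over library total and a fixed gene length, within 5.03% over 8089 genes, and that this length has a median of 0.906 of the RefSeq length. Bowtie 0.12.7 is named per the submitters' processing notes. The counting tool, the genome build and the treatment of reads with several positions are not given in the sources used here. Reads shared by near-identical genes could therefore be split, dropped or given to 1 copy, which bears on gene families such as tgr and the actins. Whether the counting used strand is likewise not given in the sources used here, so overlapping genes are uncertain. Nor is it given whether reads of replaced tgrB1 and tgrC1 alleles were counted, so values of this pair may not cover all 5 strains.

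Of 12869 identifiers, 12736 matched the RefSeq gene table of assembly dicty_2.7, which was used for symbols and for which genes neighbour each other, with no coordinates printed. The 133 unmatched identifiers took 0.605% to 1.81% of the counts and were kept in the tests under their own identifiers. Totals of 18692045 to 25590092 counts put the level of 3 counts at 0.117 to 0.16 CPM, a limit that covers counting error alone.

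Counts were tested with edgeR 4.0.16 in R 4.3.3 after TMM scaling and filterByExpr, which left 10994 genes. All 12 libraries entered 1 quasi-likelihood fit with a mean per group and robust dispersion (6 residual degrees of freedom), and p-values were adjusted by Benjamini-Hochberg at 0.05. Standard errors are the absolute log2 fold over the square root of F. Replicate libraries differed by far more than sampling noise (chi-square per degree of freedom 35.4 to 126), which rules out repeated sequencing of a single library but not separate libraries from the same RNA. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over 14 lists and 3 comparisons.

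Lists, designs, alternatives and the naming rule were fixed before the data were examined. For each comparison of arms the rule names tgrB1 and tgrC1, then the 8 highest and 8 lowest genes that passed with a symbol, a mean log2 CPM of at least 4 and no overlap between arms. It adds up to 3 passing members per list, or the most abundant member where none passed. For time courses it takes up to 2 passing members per list, and for interactions 5 genes each way. Chosen after their values were seen were dscD-1 at 4 h, pspD, cotC and the higher genes at 8 h, cprD and cprF at 12 h, and tgrB1 and tgrC1 in the time courses.

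Developmental position is the projection of log2 CPM on the line from mix 4 h to mix 12 h, over 1020 and 1262 genes (replicate 3 and 4 axes) with an absolute log2 fold and mean log2 CPM of at least 2. No library was scored on an axis it helped to make. Labels were permuted within times.

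Replicate numbers are shared by the arms, so pairing was checked before calls were compared. Deviations of same-numbered libraries from their group means correlated between arms of the same time at 0.218 to 0.594 in 3 of 3 pairs of groups, and at -0.0723 to 0.445 over 12 pairs of groups from different times. The ranges overlapped, and the lowest value for the same time, 0.218, was at 8 h, so pairing within a time was not established. A fit with a block of time and replicate number was added after seeing the data, as an alternative. The main calls come from the fit without a block.

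Alternatives were DESeq2 1.42.0 size factors and its Wald test, limma voom, no filter, a replicate block, the RPKM values on a log2 scale with a pseudocount of 1 or 0.1, a mean RPKM of at least 1, only the 4 libraries compared, a minimum fold of 2, each library left out in turn, and grouping by titles.

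The procedure was tested on simulated counts for the 8 h comparison, drawn from the real means, dispersions and library sizes. Over 10956 genes edgeR recovered 54 of 100 genes changed 2-fold and 96 of 100 changed 4-fold, with 7 false calls among 157. The fit with libraries paired within a time made 10 false calls among 155, limma voom 10 among 160 and DESeq2 23 among 189. With nothing changed edgeR made 0 calls over 10964 genes. Genes were drawn independently, with no pairing and no variation shared between genes of a library. These false calls may therefore not hold for the real libraries. A 1.5-fold rise of the 15 prespore genes was recovered by camera over 10952 genes, with 3 others of the 14 lists called as well, 1 of which shares members. A shift of -0.1 in position at 8 h was recovered as -0.0863. In 20 unchanged draws camera called 0 lists, but genes were drawn independently, so this says nothing of false calls where members are correlated (estimated correlation 0.841 for ribosomal protein genes at 8 h).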

Results

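Dictyostelium discoideum is a social amoeba whose cells feed singly and, once starved, aggregate and form a multicellular body of stalk and spore cells. TgrB1 and TgrC1 are cell-surface proteins that differ between strains and by which cells recognise kin. Polyadenylated RNA was sequenced from 5 strains, the parent AX4 and 4 strains in which the tgrB1 and tgrC1 alleles had been replaced. In 1 arm the 5 strains were developed together on filters. In the other arm, the reference, RNA of the 5 strains was mixed. Both arms were sampled at 4, 8 and 12 h with 2 biological replicates, giving 12 libraries in 6 groups. Total counts ran from 18692045 to 25590092 per library, and 10994 genes were tested. Time set the libraries apart, since the correlation of log2 CPM (counts scaled to the library total) lay between 0.985 and 0.992 for replicates and between 0.734 and 0.931 for libraries of different times. Libraries of the same time but different arms correlated at 0.982 to 0.992, from slightly below the lowest pair of replicates upward.

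The first question was whether strains with different tgr alleles, developed together, differ in expression from the same strains pooled as RNA, first at 4 h. The allorecognition genes tgrB1 and tgrC1 stood at 588 ± 479 and 278 ± 238 CPM in co-developed cells against 854 ± 425 and 412 ± 215 CPM in the RNA mix (mean ± SD, n = 2 per group). Their log2 fold changes, co-developed over mix, were -0.54 ± 0.54 and -0.57 ± 0.53 (± SE), within the spread of the replicates. Whether counts of the pair include reads of the replaced alleles is not known, at this or later times. The discoidin gene dscD-1, which encodes a lectin of early starvation, had a log2 fold of -1.03 ± 0.18, and the adhesion gene cadA one of -0.53 ± 0.25. No gene passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 4 h (0 of 10994). At an unadjusted p under 0.05 there were 191 genes, 63 higher and 128 lower. These 191 are fewer than a share of 0.05 of the 10994 tests, which chance alone would give with uniform p-values. They are thus no sign of further differences. DESeq2 called 1 gene and limma voom 0.

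Gene lists moved by small amounts at 4 h. Of 10 measured genes of early starvation, 0 passed over all genes and 3 were lower when adjusted over the list alone, with a list median of -0.23. The list was called lower by camera with a preset correlation (adjusted p = 0.00015), and the call was lost with an estimated correlation (adjusted p = 0.25). Ribosomal protein genes had a median of -0.19 with 75 of 76 below 0 (adjusted p = 2.5e-05, and adjusted p = 0.777 with an estimated correlation). Heat shock genes (median -0.14, adjusted p = 0.000293), prespore genes (median -0.31, adjusted p = 0.00675) and the other tgr genes (median -0.27, adjusted p = 0.0448) were also called lower by camera. The corresponding values were adjusted p = 0.539, 0.675 and 0.777 with an estimated correlation. The prespore call was lost without co-developed replicate 4 (adjusted p = 0.142) or mix replicate 3 (adjusted p = 0.282), and the early starvation call without mix replicate 4 (adjusted p = 0.0784). The tgr call turned to the higher side, uncalled, without co-developed replicate 4 (adjusted p = 0.125) or mix replicate 3 (adjusted p = 0.797), and was lost with a replicate block (adjusted p = 0.0821). DNA replication genes were called higher (median 0.12, adjusted p = 0.0164, and adjusted p = 0.777 with an estimated correlation), but not without co-developed replicate 4 (adjusted p = 0.509) or mix replicate 3 (adjusted p = 0.524). The tgrB1 and tgrC1 pair was not called (adjusted p = 0.074), but with libraries paired by replicate number within a time it was called lower (adjusted p = 0.000633, and adjusted p = 0.385 with an estimated correlation), as it was without co-developed replicate 3 (adjusted p = 0.00029) or mix replicate 4 (adjusted p = 0.0363). Lysosomal genes were called higher without co-developed replicate 3 (adjusted p = 0.004), and prestalk genes lower without that library (adjusted p = 0.0428) or mix replicate 4 (adjusted p = 0.04).

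At 8 h, when mounds form, the genes lower in co-developed cells included cotD and tgrM1. The spore coat gene cotD stood at 78.6 ± 23.5 CPM in co-developed cells against 415 ± 177 CPM in the mix, a log2 fold of -2.40 ± 0.34 (adjusted p = 0.0135 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 2 per group). The tgr family member tgrM1 stood at 109 ± 8.8 against 477 ± 105 CPM (-2.13 ± 0.30). The expansin-like gene expl8 fell by 1.31 ± 0.25 on the log2 scale, the kinase gene fnkB by 1.23 ± 0.20, the Rab GTPase gene rabR by 2.06 ± 0.23, and sigL-1 by 1.81 ± 0.18. The genes gnt10 and pcp had log2 folds of -1.70 ± 0.25 and -1.39 ± 0.22. By contrast tgrB1 (0.09 ± 0.54) and tgrC1 (0.00 ± 0.52) differed by less than the spread between replicates.

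In all, 76 genes passed the test at 8 h, 2 higher and 74 lower in co-developed cells, and 72 of them differed at least 2-fold. These directions follow the description field, since titles give the 8 h libraries the opposite arm. The higher genes, DDB_G0287655 (1.16 ± 0.22) and DDB_G0284931 (0.84 ± 0.16), are outside the naming rule and were picked after their values were seen. The RPKM values imply a length of 0.189 of the RefSeq length for DDB_G0284931. With libraries paired within the time the test called 259 genes, 24 higher and 235 lower, and all 76 were among them. The count was 11 without co-developed replicate 3, 3 without co-developed replicate 4, 3 without mix replicate 3 and 73 without mix replicate 4, while over 14 settings the log2 fold lay between -2.14 and -1.86 for rabR and between -2.78 and -1.89 for cotD. DESeq2 called 184 genes, the 4 libraries fitted alone gave 185, and the authors' RPKM with a pseudocount of 0.1 gave 50.

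Prespore genes, which mark future spore cells, had a median log2 fold of -0.99 at 8 h, with 13 of 15 measured members below 0. Over all genes 1 member passed (cotD), and 8 were lower when adjusted over the list alone. Members that missed the test over all genes included pspD (-2.36 ± 0.50), dcsA (-2.02 ± 0.43) and cotC (-1.43 ± 0.35). In mix replicates 3 and 4 these stood at 194 and 55.2 CPM (pspD), 94.9 and 32.4 CPM (dcsA), and 49.0 and 24.6 CPM (cotC). The log2 fold of dcsA was -1.05 without mix replicate 3 and -2.60 without mix replicate 4, its range over 14 settings. The list was called lower by camera (adjusted p = 4.8e-12), and lost the call with an estimated correlation (adjusted p = 0.25). Other tgr genes had a median of -0.47 with 28 of 32 below 0, 1 passing over all genes (tgrM1) and 7 adjusted over the list alone (adjusted p = 8.7e-10, and adjusted p = 0.539 with an estimated correlation). Prestalk genes (median -0.33, 17 of 18 below 0, 0 passing) and genes of late sporulation (median -0.40, 9 of 10 below 0, 0 passing) were called lower with adjusted p = 0.000277 and 0.00545. With an estimated correlation these gave adjusted p = 0.539 and 0.25, and 1 member of each passed when adjusted over the list alone. DNA replication genes had a median of -0.25 (adjusted p = 0.00369, and adjusted p = 0.777 with an estimated correlation). Without co-developed replicate 4 the DNA replication and late sporulation calls were lost (adjusted p = 0.0515 and 0.0647), and without mix replicate 3 the former (adjusted p = 0.847). Ribosomal protein genes were called higher (median 0.22, adjusted p = 3.8e-07, and adjusted p = 0.777 with an estimated correlation). Without co-developed replicate 3 the ribosomal call turned to lower (adjusted p = 0.0469).

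**Figure D1:**
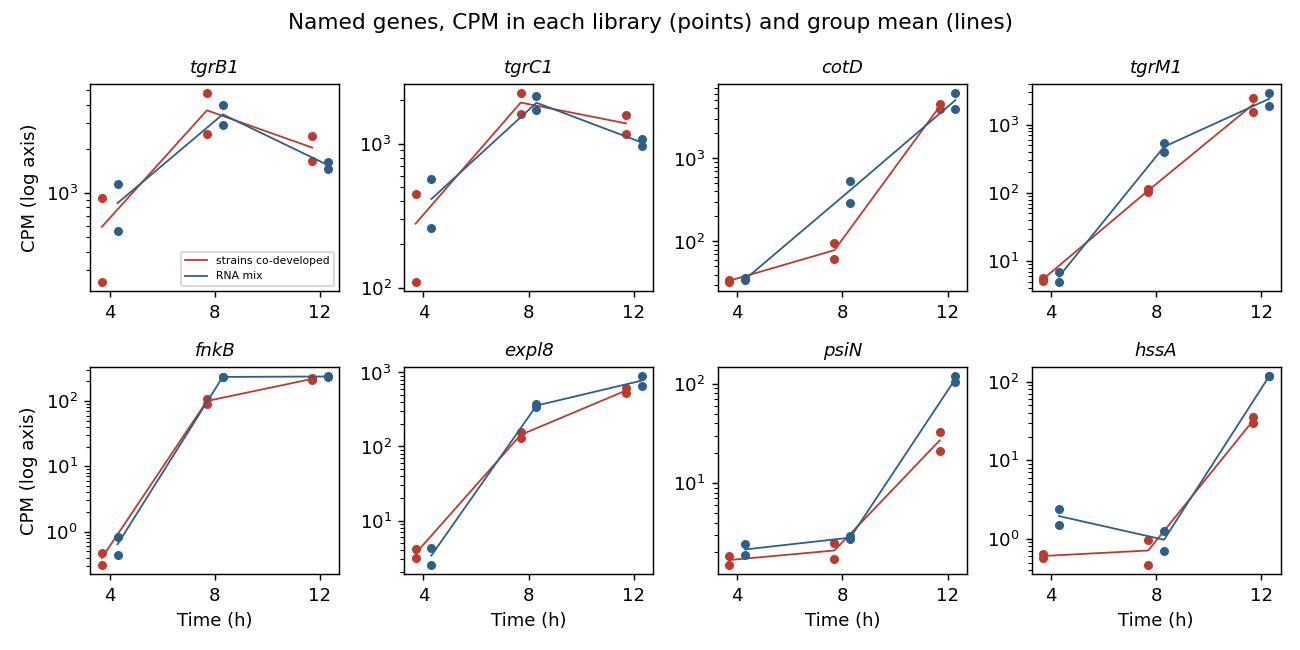
CPM (log axis) of 8 named genes against time in hours, with a point for each library and lines through the means of co-developed strains (red) and RNA mix (blue). At 8 h cotD averaged 78.6 CPM in co-developed cells and 415 CPM in the mix, while tgrB1 and tgrC1 overlapped between arms.

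At 12 h psiN, hssA and hssB were among the genes lower in co-developed cells. The gene psiN stood at 26.8 ± 8.34 CPM against 112 ± 10.3 CPM in the mix, a log2 fold of -2.06 ± 0.23 (adjusted p = 0.00611 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 2 per group). The small-protein genes hssA and hssB, which lie within 3 tested genes of each other in the dicty_2.7 assembly, fell by 1.86 ± 0.24 and 1.28 ± 0.21 on the log2 scale. The lengths implied by RPKM were 0.758 and 0.716 of their RefSeq lengths. The tgr family member tgrF1 (-1.91 ± 0.26), the transcription factor gene mybC (-1.60 ± 0.27) and the catalase gene catB (-1.54 ± 0.28) were also lower. The pair tgrB1 (0.39 ± 0.54) and tgrC1 (0.44 ± 0.52) did not pass.

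The 12 h comparison called 58 genes, 8 higher and 50 lower, and 56 of them differed at least 2-fold. With libraries paired within the time the count was 191, 42 higher and 149 lower, including all 58. It was 2 without co-developed replicate 3, 16 without co-developed replicate 4, 18 without mix replicate 3 and 17 without mix replicate 4, and 2 on the authors' RPKM with a pseudocount of 0.1. DESeq2 called 88 genes and the 4 libraries fitted alone gave 36. None of the genes called lower at 8 h was called lower at 12 h (0 shared by edgeR, against 0.337 for independent lists), while 55 of the 74 had a 12 h fold below 0 and 39 of the 50 an 8 h fold below 0.

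Among the lists at 12 h, prespore genes had a median of -0.23 with 1 of 15 passing (catB; camera adjusted p = 0.0424, and adjusted p = 0.777 with an estimated correlation). Feeding-stage lysosomal enzymes such as cprD (0.52 ± 0.37) and cprF (0.69 ± 0.46) had a median of 0.29 with 0 of 15 passing. The lysosomal list was called higher by camera (adjusted p = 0.000383, and adjusted p = 0.539 with an estimated correlation). DNA replication genes (median -0.29, 25 of 26 below 0) and heat shock genes (median -0.18) were called lower with adjusted p = 1.6e-05 and 0.0219, and with an estimated correlation gave adjusted p = 0.675 for each. Ribosomal protein genes (median 0.22) and early starvation genes (median 0.17) were called higher with adjusted p = 2.8e-09 and 0.0451, and with an estimated correlation gave adjusted p = 0.777 and 0.64. The ribosomal direction turned, uncalled, without co-developed replicate 3 (adjusted p = 0.345), and that of heat shock genes without co-developed replicate 4 (adjusted p = 0.97). Without co-developed replicate 3 the lysosomal, DNA replication, prespore and early starvation calls were also lost (adjusted p = 0.0828, 0.373, 0.442 and 0.345). Without mix replicate 4 the ribosomal, DNA replication, prespore and early starvation calls were lost (adjusted p = 0.322, 0.446, 0.446 and 0.28). The early starvation call was lost without co-developed replicate 4 (adjusted p = 0.0664) and the heat shock call without mix replicate 3 (adjusted p = 0.654). Other tgr genes were called lower without co-developed replicate 4 (adjusted p = 0.000185) or mix replicate 3 (adjusted p = 0.00801), and prestalk genes without mix replicate 3 (adjusted p = 0.0168). With libraries paired, prestalk genes were called lower (adjusted p = 0.0384) and adhesion genes higher (adjusted p = 0.0498), each with adjusted p = 0.599 with an estimated correlation.

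Lists with no camera call in any of the 3 comparisons were cAMP relay and aggregation genes (medians -0.13, 0.01 and 0.10 at 4, 8 and 12 h), post-aggregation regulators (-0.04, -0.08 and -0.02), autophagy genes (-0.03, 0.01 and -0.06), adhesion genes (-0.09, 0.05 and 0.13), and the allorecognition pair (-0.55, 0.05 and 0.42). Leaving out a library brought calls for cAMP relay genes, lower without mix 4 h replicate 3 (adjusted p = 0.000883) and higher without co-developed 8 h replicate 3 (adjusted p = 0.00809), co-developed 12 h replicate 3 (adjusted p = 0.000449) or mix 12 h replicate 4 (adjusted p = 0.0216). Post-aggregation regulators were called lower without co-developed 8 h replicate 4 (adjusted p = 0.0293) or co-developed 12 h replicate 4 (adjusted p = 0.0178), and higher without co-developed 12 h replicate 3 (adjusted p = 0.0355), when adhesion genes were also called higher (adjusted p = 0.0182). At 8 h the median and mean differed in sign for adhesion genes (0.05 and -0.10) and for heat shock genes (-0.02 and 0.02), and at 12 h camera's direction for late sporulation genes was higher while the median was -0.02. Over the 42 list tests camera called 18, 5 higher and 13 lower, and 0 were called with an estimated correlation or by fry's test of a move one way. Fry's mixed test, of change in either direction, called the prespore and late sporulation lists at 8 h (adjusted p = 0.0273 for each). Calls with a library left out were made at the preset correlation alone.

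**Figure D2:**
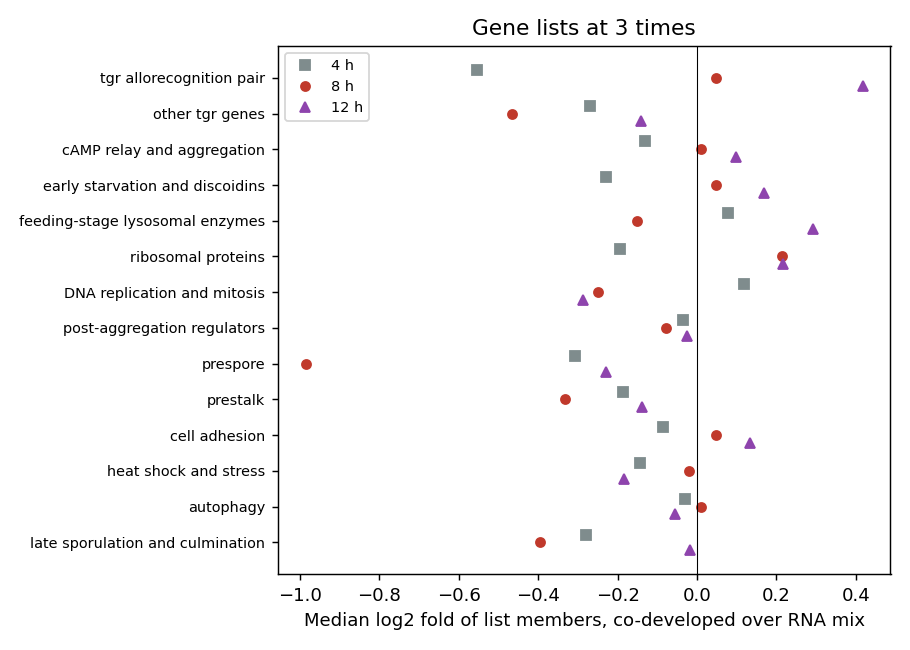
Median log2 fold (co-developed over RNA mix, x axis) of the members of each of 14 gene lists (y axis) at 4, 8 and 12 h, 1 symbol per time. The prespore list at 8 h has a median of -0.99, and the same list has -0.31 at 4 h and -0.23 at 12 h.

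Whether the effect of co-development itself differed between times was tested by interaction. The test called 0 genes for 8 h against 4 h, 0 for 12 h against 8 h and 0 for 12 h against 4 h by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 351, 501 and 246 genes. Each count is below a share of 0.05 of the tests, which chance alone would give with uniform p-values. DESeq2 called 26, 87 and 1. Limma voom called 0, 3 and 0. With libraries paired within a time the counts were 28, 137 and 0. For 12 h against 8 h the count was 14 without mix 8 h replicate 4.

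The time course in each arm supplies the background against which these differences stand. From 4 to 8 h in the mix, the cysteine protease gene cprB, of prestalk cells, rose by 6.46 ± 0.37 on the log2 scale and the regulator comH by 7.42 ± 0.32, while dscD-1 fell by 4.77 ± 0.21. Both tgrB1 (2.01 ± 0.56) and tgrC1 (2.22 ± 0.55) rose in the mix, and likewise in co-developed cells (2.63 ± 0.57 and 2.79 ± 0.56). From 8 to 12 h the prespore gene psvA rose by 8.30 ± 0.41 in the mix and 8.28 ± 0.41 in co-developed cells, and the prestalk matrix gene ecmA by 5.23 ± 0.44 and 5.37 ± 0.46. The aggregation adhesion gene csaA fell by 1.85 ± 0.28 in the mix and 2.08 ± 0.29 in co-developed cells. Of 15 prespore genes, 12 rose from 8 to 12 h in each arm, and of 26 DNA replication genes, 24 rose in each arm. Of 32 other tgr genes, 29 rose from 4 to 8 h in the mix and 27 in co-developed cells.

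From 4 to 8 h 5108 genes changed in the mix (2618 higher, 2490 lower) and 4880 in co-developed cells (2493 and 2387). From 8 to 12 h 3196 changed in the mix (2058 and 1138) and 3976 in co-developed cells (2229 and 1747). On the authors' RPKM with a pseudocount of 1 the split was 2951 higher and 1784 lower for the mix from 4 to 8 h, and 2511 and 1206 for co-developed cells from 8 to 12 h. With a mean RPKM of at least 1 the median fold of all genes from 4 to 8 h in the mix was 0.10, with 2950 higher and 1814 lower.

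Each library was placed on the course of the RNA mix, with 0 for the mix at 4 h and 1 for the mix at 12 h, over genes that changed at least 4-fold. At 8 h co-developed cells stood at 0.415 ± 0.015 and the mix at 0.527 ± 0.0404 (mean ± SD, n = 2), a difference of -0.112, with both co-developed libraries below both mix libraries. At 4 h the positions were -0.0306 ± 0.0435 and 0.00143 ± 0.102, and at 12 h 0.957 ± 0.045 and 1.00 ± 0.0948, differences within the spread of the replicates when libraries are not paired. Paired by replicate number within a time, the co-developed library stood lower in 5 of 6 pairs (two-sided exact permutation p = 0.0938). Over the 3 times the mean difference was -0.0626 (two-sided exact permutation p = 0.0926). At a single time 2 against 2 libraries allow no exact permutation p below 0.333. Co-developed libraries were scored on both axes and mix libraries on 1, so labels were not strictly exchangeable in these permutations. With every library scored only on the axis of the other replicate number, the difference was -0.0619 (exact permutation p = 0.157). Dropping the score of 1 library left the axes unchanged, so a dropped mix library of 4 or 12 h still shaped the other scores. The mean difference then ranged from -0.0867 (without mix 4 h replicate 4) to -0.0386 (without mix 4 h replicate 3). The sign turned at 4 h without mix replicate 3 (0.04) and at 12 h without mix replicate 4 (0.023).

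**Figure D3:**
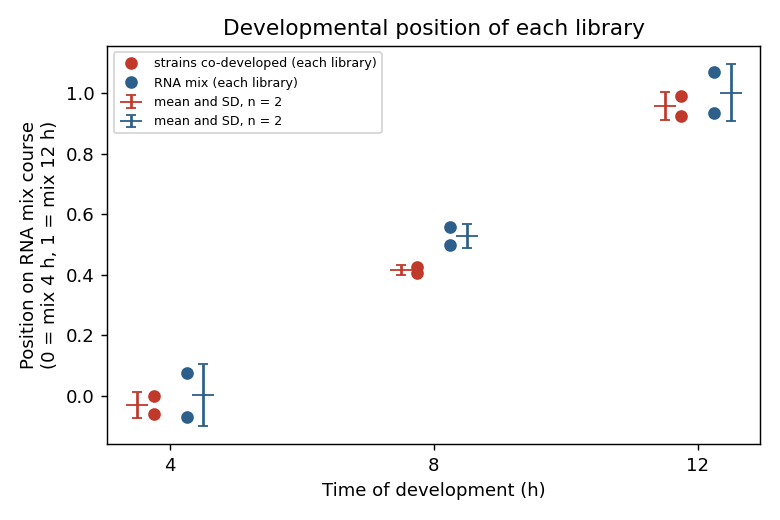
Position of each library on the RNA mix course (y axis, 0 for mix 4 h and 1 for mix 12 h) against time in hours, with a point per library and bars for mean and SD (n = 2) of co-developed strains (red) and RNA mix (blue). At 8 h the means are 0.415 and 0.527.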

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

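All tests of explanations in this part were chosen after the results were seen.

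The co-development effect differed between times in 15 list tests by camera with a preset correlation, and 0 of them held with an estimated correlation. For 8 h against 4 h, the median difference in log2 fold was 0.41 for early starvation genes, 0.41 for ribosomal protein genes, -0.40 for DNA replication genes, -0.50 for prespore genes, -0.35 for prestalk genes and 0.25 for heat shock genes. For 12 h against 8 h it was 0.50 for other tgr genes, 0.42 for lysosomal enzymes, 0.67 for prespore genes, -0.24 for heat shock genes and 0.35 for late sporulation genes. For 12 h against 4 h it was 0.19 for cAMP relay genes, 0.33 for early starvation genes, 0.41 for ribosomal protein genes and -0.44 for DNA replication genes.

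Nearly all genes called at 8 h were lower in co-developed cells (74 of 76). A scaling factor shared by all genes is argued against as the whole cause, since it cannot alter which side of the median fold genes lie on, and 98.0% of the 198 genes more than 1 (log2) from it lay below; a first bound, dropped after the value was seen, had also asked for more one-sidedness than in the other pairings of these 4 libraries (95% of 40 genes and 100% of 9) and was missed. An earlier point of the developmental course is a candidate explanation. Of the 74 genes 100% were higher at 12 h than at 4 h, against a median of 48.6% in 10000 random sets matched on mean expression. The 4 and 12 h libraries were outside the 8 h contrast but shared its fit. All 74 genes also rose from 4 to 8 h in the mix. Anything that lowers genes rising by 8 h would thus give a like share, so the share cannot single out timing. Of the 2 genes called higher at 8 h, 0 were lower at 12 h than at 4 h, which an earlier point alone would not give. The shift was not confined to called genes, since 1509 uncalled genes that rose at least 4-fold from 4 to 12 h had a median 8 h fold of -0.336, and 1214 of them were below 0. Slower development, a difference in harvest time and unequal growth of the 5 strains stay open and were not tested. The direction also depends on the arms named in the description, which titles contradict at 8 h.

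Calls at 12 h were mostly lower in co-developed cells and lay close together, while at 8 h 11 of 76 called genes had a called neighbour (random median 2, permutation p = 0.005). Of 58 called genes, 22 had another called gene among the 3 tested genes on either side in dicty_2.7. That was more than in any of 10000 expression-matched random sets (highest 14, permutation p = 0.0001, the smallest they can give). Chance placement among genes of like expression is therefore argued against. The sets were not matched on time course, and 48 of the 50 lower genes rose from 8 to 12 h in the mix. Whether late-rising genes lie close together whatever the arm was not tested. Reads shared between near-identical copies cannot be told apart from joint regulation: the length implied by the RPKM values had a median of 0.725 of the RefSeq length in 20 such genes, against 0.9 in matched sets, but actins, the intended yardstick, had 0.536. Late onset with slower progress may contribute, since 88% of the 50 lower genes rose from 8 to 12 h in co-developed cells, against 22% in matched sets. That comparison shares the 12 h co-developed libraries with the calls.

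Ribosomal protein genes were called higher in co-developed cells at 8 h with a preset correlation, and not with an estimated correlation (adjusted p = 0.777 with an estimated correlation). The share of counts was higher in co-developed replicate 3 by 4.54 percentage points but differed by -0.543 points in replicate 4, so a single library is a candidate explanation. No biological explanation was tested.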

How the results depend on the processing

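The fit with a block of time and replicate number and the position axes from 4 to 8 h and from 8 to 12 h were chosen after seeing the data. So was the scoring of every library on the axis of the other replicate number only. With 2 libraries per group, leaving 1 out assumes that the lone library varies like the other groups. The cause was not tested for any change given here. Leaving out libraries or using 4 of them lowers the sample number. That alone does not account for counts that rose, such as 76 to 185 at 8 h with only the 4 libraries. Results for single named genes were mostly time-course results, and arm results uncalled in the main fit kept their side by staying uncalled. Over all of them 1874 kept their side of the threshold, 135 fell short of it, mostly with a library left out, and 3 newly passed. No named gene that passed changed sign outside grouping by titles. The totals do not measure how stable calls between arms are. Of the 58 genes called at 12 h, 30 were called again with only the 4 libraries and 0 on RPKM with a pseudocount of 0.1. Of the 76 called at 8 h, 75 and 42 were. Other settings with all libraries kept at least 50 and 66.

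At 4 h the count of 0 became 1 by DESeq2 and 4880 by titles. At 8 h the count of 76 became 184 by DESeq2, 259 with the replicate block within time, 50 on RPKM with a pseudocount of 0.1, 185 with only the 4 libraries and 6472 by titles, and ranged from 3 to 73 with a library left out. At 12 h the count of 58 became 88, 191, 2, 36 and 3196 under the same settings, and ranged from 2 to 18. The replicate block without time gave 88 at 8 h and 77 at 12 h, and changed no count of the arms by over 1.5 times.

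Interactions, 0 each, became 26 (8 h against 4 h), 87 (12 h against 8 h) and 1 (12 h against 4 h) by DESeq2, 28 and 137 for the first 2 with the block within time, and 7056, 6462 and 4305 by titles. For 12 h against 8 h other settings gave 5 (DESeq2 size factors), 3 (limma voom), 17 (replicate block), 39 (RPKM) and 33 (RPKM of at least 1), with 0 to 14 when a library was left out, the 14 without mix 8 h replicate 4. For 12 h against 4 h RPKM gave 13 and 10.

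Requiring a 2-fold change left 2707 and 1899 genes in the mix (4 to 8 h, 8 to 12 h) and 2558 and 2244 in co-developed cells. With a library left out the ranges were 3178 to 3872, 1891 to 2547, 3245 to 4246 and 2743 to 3707, and titles gave 6651 for the mix from 8 to 12 h. The 18 list calls became 0 with an estimated correlation, with or without the block within time, 21 with that block at the preset correlation, and 13 to 21 with a library left out.

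The position difference ranged from -0.0867 to -0.0386 with a library left out (exact permutation p 0.0278 to 0.296). On falling genes alone it was -0.0345 (exact permutation p = 0.38), with 0.0118 at 4 h. At 8 h it was -0.0756 on falling genes and -0.152 on the axis from 8 to 12 h, and -0.14 to -0.0833 with a score dropped. With a score dropped it ranged at 4 h from -0.104 to 0.04 and at 12 h from -0.111 to 0.023.

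Title groups hold the same pairs of libraries under other labels, so comparisons by titles set libraries of different described times against each other. Under titles 63 of 114 called named results took the opposite sign. Values of single genes by titles are not tabulated.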

Other observations

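The test in this part, over groups of genes sharing a symbol prefix, was chosen after the data were seen. At 8 h the 32 act genes, mostly actins, had a median log2 fold of 0.43 in co-developed cells (camera with a preset correlation, Benjamini-Hochberg adjusted p = 5.5e-05), and the 19 ddx helicase genes one of 0.29 (adjusted p = 9.1e-05). The 6 psp genes, of prespore cells, had a median of -1.21 (adjusted p = 4.4e-06). At 12 h the 9 cup genes had a median of 0.53 and the 7 ecm genes, of the prestalk matrix, one of -0.83 (adjusted p = 4.4e-06 for each). The 40 psm proteasome genes had medians of -0.28 at 4 h and -0.25 at 12 h (adjusted p = 6.2e-12 and 2.2e-05). None of these held with an estimated correlation (adjusted p = 0.966, and 0.887 for ecm), and over the 3 times edgeR called 0 single act, ddx, psp, cup or psm genes either way and 1 ecm gene, ecmH, lower at 12 h (-2.11 ± 0.35).

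Genes named as the second copy of the duplicated stretch of chromosome, with symbols ending in -2, took 2909 counts over the 12 libraries, while those ending in -1 took 7022666. Counts were thus not split evenly between these copies.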
